A study of Mus musculus with 103 samples.

How the data were processed

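Sorted cells, primary tumours and metastases of mice were measured on 103 Affymetrix mouse 430 arrays with perfect match probes, 1 array per sample. Per the labels' protocols, organs were dissociated, red cells lysed, dead cells removed, and cells bound by magnetic beads against Prominin1 extracted with a PicoPure kit, while tumours and metastases were dissected and extracted with an RNeasy Mini kit. Labelled cRNA was made by the manufacturer's standard protocol. The values were deposited on the log2 scale, as read from their range of 1.85 to 14.36. Per the submitters' processing notes Partek 6.6 was used, and the background correction, normalization and summarization are not given in the sources used here. Array medians lay between 3.81 and 4.24 and 75th percentiles between 5.76 and 6.71. Group means of the latter were lowest in lung (6.21, samples 5.76 to 6.68), stomach (6.24) and untreated liver cells (6.25). No further scaling was applied. Every column was used, and the closest pair of arrays had a Pearson r of 0.993 with differences of up to 1.75, so no array was a copy of another.

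Of 45141 probe sets, 104 controls, 551 annotated to several genes and 15588 missing from the annotation used here were left out of the gene tests. The remaining 28898 probe sets named 17097 genes, and the probe set with the highest mean stood for each gene. By gene number, 28689 of them matched RefSeq. The array annotation names no genome build, so no coordinates are given. Samples were grouped by the labels into 29 groups. Control probe sets gave the 3' minus 5' difference of actin and Gapdh per array, which grows with RNA degradation.

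Differences were fitted with limma 3.58.1 in R 4.3.3, with version 1.17.8 of data.table, by lmFit, contrasts and empirical Bayes moderation with an intensity trend, and p-values were adjusted by Benjamini-Hochberg within each comparison. Genes were tested when their mean in at least 1 compared group exceeded the 40th percentile of the fitted values. A gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1. Comparisons of sorted cells were fitted over all 40 sorted samples, with 30 residual degrees of freedom, tumours against sorted cells over the compared groups alone, and tumours against tumours over 55 primary tumours, with 44. Each of 50 gene lists (20 pathway and 30 cell type lists, 626 genes of which 538 were measured) was tested with camera at a preset correlation of 0.01, adjusted over all 1033 tests of a list in a comparison, and again with the correlation estimated per list. The mean log2 level of a list's members is called its score. Correlations between samples were tested by exact permutation, and nearest organs by 100000 permutations of the organ labels. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

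The groups, comparisons, thresholds, gene lists, alternative settings and the rule for named genes were fixed before the data were examined. The rule names Prom1, the 10 largest increases and decreases among called genes whose samples in the 2 groups do not overlap, the 5 largest differences per organ, and up to 4 members with the largest difference for each list described. Genes without a single symbol were not named, and named genes whose call was lost in a setting or with a sample left out were not described, except for Gast in gastric adenoma and Chil4 in lung, given with that change, and for hepatoblastoma against neonatal cells, where leaving out neonatal sample 1 or 3 removed every call. Of the lists called and kept with each sample left out only a part is described, with 2 lists that were not called, all chosen after their values were seen. Levels under the filter value, which was 4.06 for sorted cells, are near the background of the array, so differences against such levels are lower bounds. Alternatives were quantile normalization, median centring, no filter or a 60th percentile filter, the mean of a gene's probe sets, probe sets named for cross-hybridisation left out, other samples in the fit, array weights, a robust prior, each sample left out in turn, and limits on the title number as a proxy for processing order. Settings added after seeing the data are named as such where they are used.

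In simulations a log2 change of 2 was recovered in 7% (lung adenocarcinoma) to 94% of changed genes, one of 3 in 44% to 100%. At most 12 unchanged genes were called, but up to 1799 higher (median 0) in 100 neonatal simulations without difference. With unchanged groups, the preset list test called a mean of 7.2 of 43 lists for HCC/CC and 7.8 of 49 for small intestinal adenoma. An estimated correlation gave 0. Of 1033 list tests, 321 were called with the preset and 35 with the estimated correlation. Samples of a group are numbered here in the order of their labels, which give no pairs and no batches.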

Results

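The 103 samples fell into 29 groups. Of these, 40 were cells sorted with magnetic beads against Prominin1, the membrane protein encoded by Prom1, from 8 organs of mice, 56 were dissected primary tumours and 7 were dissected metastases. The design text describes lineage tracing and oncogenic targeting of cells that express Prom1. Sorted cells were compared between organs and by age and injury in liver, and tumours with sorted cells of their organ. Sorted cells came from kidney (n = 4), untreated liver (n = 5), liver after DDC (n = 9), a compound used to injure liver and bile ducts, neonatal liver (n = 3), lung (n = 4), prostate (n = 3), salivary gland (n = 3), small intestine (n = 3), stomach (n = 2) and uterus (n = 4). Primary tumours were hepatocellular carcinoma/cholangiocarcinoma (HCC/CC, n = 14), hepatoblastoma (n = 2), prostatic adenocarcinoma (n = 8), gastric adenoma (n = 7), gastric adenocarcinoma (n = 4), small (n = 3) and large (n = 5) intestinal adenoma, uterine carcinoma (n = 3), lung adenocarcinoma (n = 2), and squamous cell carcinoma of perineal (n = 4), perioral (n = 3) and periorbital (n = 1) skin. The labels do not say whether samples of a group came from separate animals, so p-values measure only the spread between samples, which may be technical.

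Values are log2 levels (mean ± SD) or log2 differences ± the standard error of limma, and the median of a gene list is that of its members' log2 differences. Only called genes are said to rise or fall. Gene lists were tested with camera at a preset correlation between genes, which also called lists in simulated groups with no difference, so each list is given with its p under an estimated correlation.

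Prom1 (Entrez gene 19126), the gene whose protein was used for the sort, had its highest mean level among sorted cells in stomach, at 11.99 ± 0.29, and uterus, at 11.54 ± 0.47. It was 10.76 ± 0.06 in kidney, 10.55 ± 0.09 in salivary gland, 10.31 ± 0.45 in prostate and 9.33 ± 1.15 in small intestine, but only 6.36 ± 0.71 in lung and 3.45 ± 0.67 in untreated liver, the last under the filter value of 4.06. Lung cells 3 stood apart at 5.30. Neonatal liver cells held 10.29 ± 0.08 and cells of DDC-treated liver 7.04 ± 2.27, with samples from 3.31 to 9.31. Among tumours the level was 11.34 ± 0.65 in small intestinal adenoma, 10.12 ± 3.27 in gastric adenoma (2.87 in sample 3), 9.37 ± 1.11 in prostatic adenocarcinoma, 8.92 ± 0.98 in hepatoblastoma and 7.08 ± 2.39 in HCC/CC. The spread was wide in uterine carcinoma (7.63 ± 4.35) and large intestinal adenoma (6.20 ± 4.42), and the level was low in perineal (3.72 ± 0.52) and perioral (3.19 ± 0.61) squamous cell carcinoma.

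**Figure D1:**
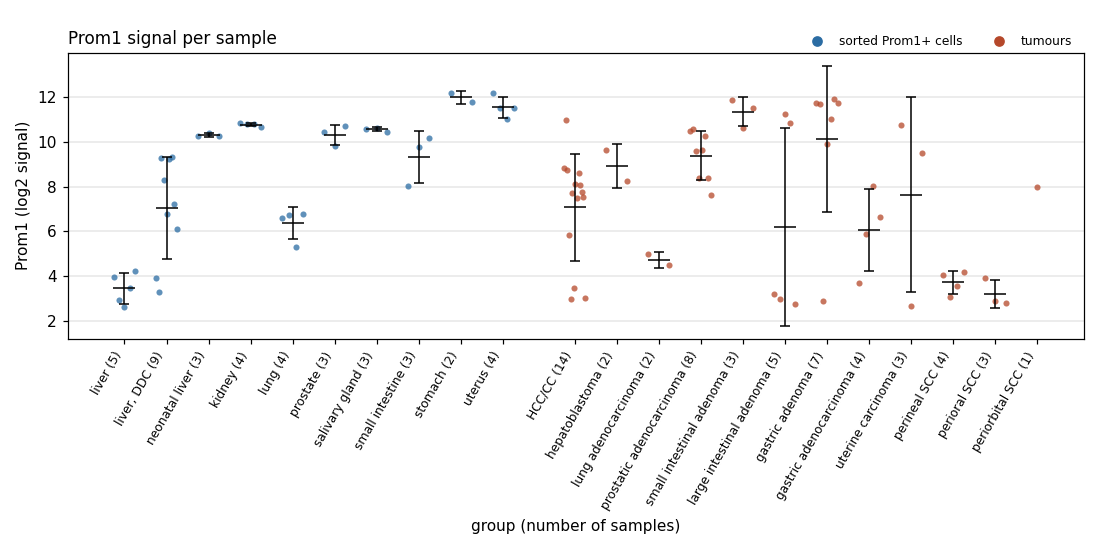
Prom1 level (log2, vertical axis) of every sample by group (horizontal axis), with the mean and SD of each group. Untreated liver cells lie at 3.45 ± 0.67 (n = 5) and neonatal liver cells at 10.29 ± 0.08 (n = 3).

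Sorted cells of each organ were compared with the mean of the other 7 organs. Kidney cells had 2139 genes higher, led by Umod, the uromodulin of the thick ascending limb (10.32 ± 0.12), Slc12a1, its sodium, potassium and chloride transporter (9.67 ± 0.14), Miox (9.67 ± 0.27), Cltrn (9.57 ± 0.31) and Slc5a12 (8.99 ± 0.34). Among proximal tubule markers, 9 of 9 tested were higher and 0 lower (9 and 0 adjusted over the list alone, median 8.38, adjusted p = 4.6e-16, adjusted p = 1.9e-04 with an estimated correlation). Untreated liver cells had 1324 genes higher, with Serpina1a (10.12 ± 0.22), Serpina1b (9.88 ± 0.34), Serpina1c (9.55 ± 0.67), Fgb (9.54 ± 0.26) and Ces3b (9.24 ± 0.48) in front, mostly secreted plasma proteins of hepatocytes. Among hepatocyte markers, 14 of 14 tested were higher and 0 lower (14 and 0 adjusted over the list alone, median 7.59, adjusted p = 2.6e-24, adjusted p = 0.019 with an estimated correlation). Among endothelial markers, 12 of 14 tested were higher and 0 lower (12 and 0 adjusted over the list alone, median 2.77, adjusted p = 7.2e-06, adjusted p = 0.52 with an estimated correlation). Lung cells had 1677 genes higher, including Sftpc, a surfactant protein of alveolar type 2 cells (9.06 ± 0.43), Scgb1a1, a secretoglobin of club cells (8.29 ± 0.28), and the eosinophil and macrophage products Chil3 (8.65 ± 0.57) and Ear3 (7.93 ± 0.63). Chil4 also led there (7.46 ± 0.47), but its value was -0.30 without probe sets that can hybridise with several transcripts. Among alveolar type 2 markers, 8 of 10 tested were higher and 0 lower (8 and 0 adjusted over the list alone, median 2.38, adjusted p = 1.5e-06, adjusted p = 0.0020 with an estimated correlation). Among endothelial markers, 14 of 14 tested were higher and 0 lower (14 and 0 adjusted over the list alone, median 3.61, adjusted p = 1.3e-08, adjusted p = 0.39 with an estimated correlation). Among macrophage markers, 12 of 13 tested were higher and 0 lower (12 and 0 adjusted over the list alone, median 2.66, adjusted p = 2.0e-05, adjusted p = 0.50 with an estimated correlation).

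Prostate cells had 1369 genes higher, with the secretory genes Svs4 (10.43 ± 0.32), Pbsn (10.40 ± 0.43), Svs2 (10.38 ± 0.33), Pate4 (10.26 ± 0.21) and Sbp (10.24 ± 0.31) first, which encode proteins of seminal fluid or prostatic secretion. Among prostate luminal markers, 10 of 12 tested were higher and 0 lower (10 and 0 adjusted over the list alone, median 5.23, adjusted p = 1.6e-17, adjusted p = 5.9e-04 with an estimated correlation). Salivary gland cells had 1423 genes higher, led by Bpifa2 (10.83 ± 0.20), Mucl2 (10.74 ± 0.19), Cst10 (10.63 ± 0.14), Klk1b26 (10.56 ± 0.14) and Smr3a (10.53 ± 0.13). Among salivary acinar and duct markers, 10 of 10 tested were higher and 0 lower (10 and 0 adjusted over the list alone, median 7.28, adjusted p = 1.2e-23, adjusted p = 1.5e-08 with an estimated correlation). Of the immediate early genes, which respond to stimulation within minutes, 14 of 17 tested were higher and 0 lower (16 and 0 adjusted over the list alone, median 1.85, adjusted p = 1.2e-08, adjusted p = 0.13 with an estimated correlation). Small intestinal cells had 1870 genes higher, including the Paneth cell defensin Defa39 (9.003 ± 0.22), Reg1 (8.92 ± 0.62), the brush border enzyme Alpi (8.88 ± 0.27), Adh6a (8.84 ± 0.20) and the fatty acid binding protein Fabp2 (8.55 ± 0.60). Among enterocyte markers, 12 of 12 tested were higher and 0 lower (12 and 0 adjusted over the list alone, median 6.21, adjusted p = 9.5e-17, adjusted p = 0.014 with an estimated correlation). Stomach cells had 1190 genes higher, led by gastrin, Gast (9.72 ± 0.33), the intrinsic factor gene Cblif (9.58 ± 0.20), the pepsinogen gene Pgc (9.42 ± 0.26) and the gastrokines Gkn2 (9.38 ± 0.44) and Gkn3 (9.11 ± 0.79). Among chief and neck cell markers, 7 of 8 tested were higher and 0 lower (7 and 0 adjusted over the list alone, median 7.61, adjusted p = 9.5e-17, adjusted p = 3.9e-06 with an estimated correlation). Uterine cells had 2003 genes higher, with Sprr2f (8.99 ± 0.27), Prap1 (7.99 ± 0.26), Bcat1 (7.76 ± 0.16), Padi1 (7.06 ± 0.16) and Lcn2 (6.95 ± 0.46). Among uterine epithelial markers, 10 of 11 tested were higher and 0 lower (10 and 0 adjusted over the list alone, median 3.70, adjusted p = 2.0e-13, adjusted p = 1.5e-06 with an estimated correlation). In the same cells 17 of 17 tested extracellular matrix genes were higher and 0 lower (17 and 0 adjusted over the list alone, median 4.51, adjusted p = 6.3e-14, adjusted p = 0.047 with an estimated correlation). Among stellate cell and fibroblast markers, 12 of 14 tested were higher and 0 lower (13 and 0 adjusted over the list alone, median 2.45, adjusted p = 1.2e-08, adjusted p = 0.065 with an estimated correlation). Among smooth muscle markers, 7 of 8 tested were higher and 0 lower (7 and 0 adjusted over the list alone, median 2.40, adjusted p = 4.2e-07, adjusted p = 0.017 with an estimated correlation). Among macrophage markers, 8 of 13 tested were higher and 1 lower (8 and 1 adjusted over the list alone, median 3.40, adjusted p = 0.0044, adjusted p = 0.67 with an estimated correlation). Among cytokine and chemokine genes, 14 of 16 tested were higher and 0 lower (14 and 0 adjusted over the list alone, median 3.97, adjusted p = 5.3e-06, adjusted p = 0.33 with an estimated correlation). Genes named for an organ had adjusted p of 2.9e-11 or lower. The median difference of all genes moved from -0.23 to -0.35 in lung after median centring and from 0.08 to -0.07 in uterus after quantile normalization.

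Proliferation genes separated the sorted groups into organs with low and high levels. Their mean level was 3.75 in kidney, 3.86 in untreated liver, 3.88 in prostate, 4.26 in salivary gland and 4.62 in lung. It was 6.21 in uterus, 7.20 in stomach and 7.99 in small intestine. In small intestine, 20 of 21 tested were higher and 0 lower (20 and 0 adjusted over the list alone, median 3.29, adjusted p = 4.5e-11, adjusted p = 0.35 with an estimated correlation). Kidney cells lay at the other end, where 0 of 21 tested were higher and 18 lower (0 and 18 adjusted over the list alone, median -1.52, adjusted p = 2.2e-04, adjusted p = 0.62 with an estimated correlation). Neonatal liver reached 7.72 and DDC-treated liver 5.77.

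**Figure D2:**
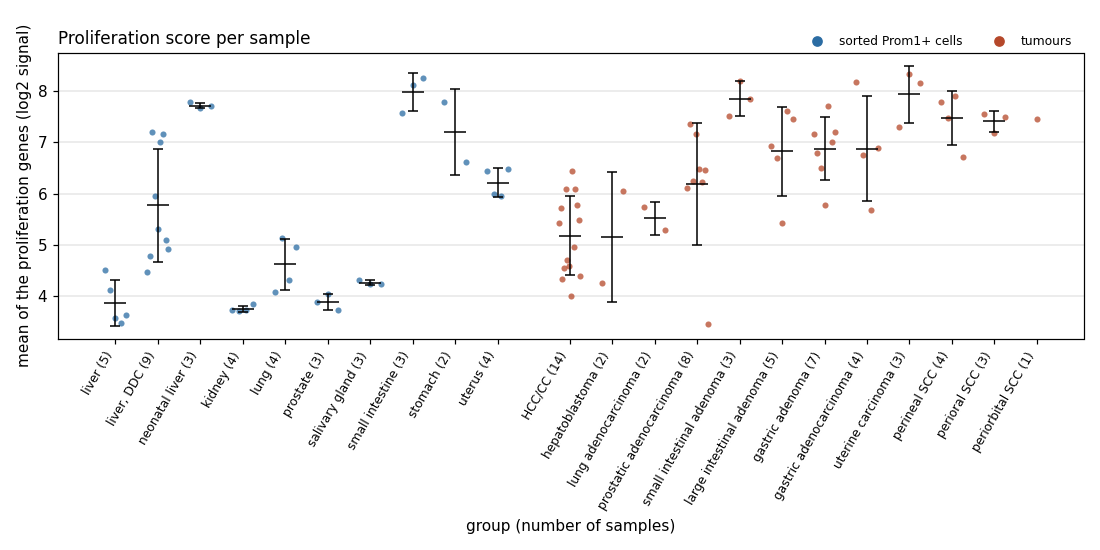
Mean log2 level of the proliferation genes (vertical axis) in every sample by group (horizontal axis), with the mean and SD of each group. Kidney cells lie at 3.75 and small intestinal cells at 7.99.

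Sorted cells of neonatal liver (n = 3) were compared with those of untreated older liver (n = 5). Afp, the fetal serum protein, was 13.54 ± 0.10 against 2.80 ± 0.43, a difference of 10.74 ± 0.49. Further genes that rose were Bex1 (9.07 ± 0.78), Igf2 (8.34 ± 0.34), Cyp3a16 (7.96 ± 0.18) and Sult2a2 (7.83 ± 0.52), of which Igf2 is an imprinted growth factor, together with the noncoding RNA Rian (7.05 ± 0.64), the neutrophil granule gene Ngp (6.85 ± 0.41), Hao2 (6.74 ± 0.41) and Enah (6.59 ± 0.57), and Prom1 itself (6.84 ± 0.87). Genes that fell were the major urinary protein gene Mup3 (-10.19 ± 0.64), the cytochrome P450 genes Cyp2c29 (-8.59 ± 0.33) and Cyp2d13 (-6.69 ± 0.66), the lipogenic genes Thrsp (-7.67 ± 0.69) and Elovl3 (-7.01 ± 0.35), the steroid dehydrogenase Hsd3b5 (-7.34 ± 0.23), the bile salt and organic anion carrier Slco1a1 (-6.63 ± 0.31), and Pigr (-7.01 ± 0.54) and Serpina12 (-6.54 ± 0.66). The Afp (2.80) and Prom1 (3.45) levels of untreated cells lay under the filter value of 4.06, so these 2 differences are lower bounds. All of these had adjusted p values of 1.6e-07 or lower with limma.

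Among oncofetal liver genes, 8 of 10 tested rose and 0 fell (8 and 0 adjusted over the list alone, median 5.64, adjusted p = 1.2e-08, adjusted p = 0.0049 with an estimated correlation). Beside Afp, Tff3 (6.40 ± 0.61) and Bex1 (9.07 ± 0.78) rose. Among proliferation genes, 20 of 20 tested rose and 0 fell (20 and 0 adjusted over the list alone, median 4.01, adjusted p = 4.0e-12, adjusted p = 0.33 with an estimated correlation). Examples were Ube2c (5.76 ± 0.68), Birc5 (5.39 ± 0.68), Ccnb2 (5.27 ± 0.67) and Mki67 (5.25 ± 0.67). Among DNA replication genes, 21 of 22 tested rose and 1 fell (21 and 1 adjusted over the list alone, median 2.77, adjusted p = 1.5e-09, adjusted p = 0.25 with an estimated correlation). Examples were Rrm2 (5.01 ± 0.58) and Mcm6 (4.89 ± 0.43). Among cholangiocyte markers, 9 of 11 tested rose and 0 fell (9 and 0 adjusted over the list alone, median 3.95, adjusted p = 0.0014, adjusted p = 0.39 with an estimated correlation). Examples were Epcam (6.34 ± 0.85) and Krt19 (4.11 ± 0.78). Among genes of bile acid and cytochrome P450 metabolism, 0 of 14 tested rose and 7 fell (0 and 8 adjusted over the list alone, median -2.07, adjusted p = 1.2e-05, adjusted p = 0.39 with an estimated correlation). Cyp7b1, an oxysterol hydroxylase of bile acid synthesis, differed by -5.46 ± 0.47. Among neutrophil markers, 6 of 8 tested rose and 0 fell (6 and 0 adjusted over the list alone, median 4.90, adjusted p = 0.0018, adjusted p = 0.32 with an estimated correlation). The difference between 3' and 5' actin probe sets, a sign of RNA quality, was 0.80 ± 0.07 in neonatal and 1.45 ± 0.25 in untreated liver cells. In total 3434 of 11197 genes were called, 2468 higher and 966 lower (71.9% higher), and 1959 higher and 1399 lower (58.3%) after quantile normalization, which moved the median of all genes from 0.31 to 0.09. With untreated liver sample 1 as the only control, an alternative chosen after seeing the data, 1450 genes were called (59.0% higher).

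Liver cells after DDC (n = 9) were compared with those of untreated liver (n = 5). Lcn2, a siderophore-binding protein of acute inflammation, was 11.83 ± 0.87 against 4.74 ± 1.58, a difference of 7.09 ± 0.47. The macrophage metalloelastase Mmp12 (5.17 ± 0.52), the ubiquitin-like Ubd (5.25 ± 0.46), the cornified envelope gene Sprr1a (5.43 ± 0.56), the chemokine Cxcl14 (5.13 ± 0.39), and Cpe (5.20 ± 0.43), Ear3 (4.85 ± 0.65) and Steap2 (4.42 ± 0.32) also rose. The transcript Gt(ROSA)26Sor, from a locus often used for transgenes, rose by 5.46 ± 0.48, and Prom1 by 3.59 ± 0.67. Genes that fell were Mup3 (-8.35 ± 0.49), Hsd3b5 (-7.71 ± 0.17), Elovl3 (-6.95 ± 0.27), Slco1a1 (-6.67 ± 0.24) and Sult2a8 (-6.65 ± 0.33), the cytochromes Cyp4a12a (-6.56 ± 0.51), Cyp8b1 (-4.97 ± 0.33) and Cyp2d13 (-4.92 ± 0.51), of which Cyp8b1 is the sterol hydroxylase of cholic acid synthesis, and Ces3b (-4.51 ± 0.54). The largest adjusted p among these genes was 6.4e-05.

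Among proliferation genes, 17 of 19 tested rose and 0 fell (17 and 0 adjusted over the list alone, median 2.04, adjusted p = 5.7e-06, adjusted p = 0.54 with an estimated correlation). Examples were Ccnb2 (3.38 ± 0.51) and Mki67 (2.94 ± 0.51). Among DNA replication genes, 15 of 21 tested rose and 1 fell (15 and 1 adjusted over the list alone, median 1.69, adjusted p = 1.3e-05, adjusted p = 0.44 with an estimated correlation). Mcm10 was the member that fell (-2.85 ± 0.45), while Cdt1 rose (3.69 ± 0.31). Among cytokine and chemokine genes, 3 of 13 tested rose and 0 fell (3 and 0 adjusted over the list alone, median 0.84, adjusted p = 0.35, adjusted p = 0.85 with an estimated correlation), so this list was not called. Among oxidative and xenobiotic response genes, 9 of 15 tested rose and 0 fell (9 and 0 adjusted over the list alone, median 1.70, adjusted p = 8.8e-04, adjusted p = 0.36 with an estimated correlation), including the glutathione transferase Gsta2 (4.24 ± 0.45) and the carbonyl reductase Cbr3 (3.16 ± 0.30). Among heat shock genes, 0 of 9 tested rose and 4 fell (0 and 4 adjusted over the list alone, median -0.61, adjusted p = 5.6e-05, adjusted p = 0.19 with an estimated correlation). Examples were Hspa1b (-3.52 ± 0.33) and Hspb1 (-3.44 ± 0.40). Among bile acid and cytochrome P450 genes, 2 of 14 tested rose and 6 fell (2 and 6 adjusted over the list alone, median -0.92, adjusted p = 0.012, adjusted p = 0.64 with an estimated correlation), and Cyp2b10 was among those that rose (3.55 ± 0.69). The actin 3' minus 5' difference was 0.997 ± 0.35 after DDC and 1.45 ± 0.25 without. The comparison called 2372 of 10919 genes, 1773 higher and 599 lower (74.8% higher), and 1333 higher and 919 lower (59.2%) after quantile normalization, with a median of all genes of 0.25 and 0.06. Untreated liver sample 1 as the only control, chosen after seeing the data, left 430 called genes (52.8% higher).

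DDC-treated samples differed widely in Prom1, and the level moved with markers of other cell types and with RNA quality. Across the 9 samples, Prom1 and the macrophage score had a Pearson r of -0.93 (exact permutation p = 2.8e-04, adjusted p = 0.0017 over 6 relations) and a Spearman rho of -0.95 (p = 3.5e-04, adjusted 0.0011, exact permutation). Without the 2 samples farthest from the median of the macrophage score r was -0.915. The proliferation score gave r = 0.90 (exact permutation p = 0.0011, adjusted p = 0.0032) and rho = 0.95 (p = 3.5e-04, adjusted 0.0011), with r = 0.86 after leaving out 2. For cholangiocyte markers r was 0.87 (exact permutation p = 0.0028, adjusted p = 0.0034) and rho 0.87 (p = 0.0045, adjusted 0.0054), with r = 0.87 after leaving out 2. For hepatocyte markers r was 0.875 (exact permutation p = 0.0021, adjusted p = 0.0032) and rho 0.92 (p = 0.0013, adjusted 0.0026), but r fell to 0.59 after leaving out 2, so much of it rests on those samples. The actin 3' minus 5' difference gave r = 0.89 (exact permutation p = 0.0018, adjusted p = 0.0032) and rho = 0.87 (p = 0.0045, adjusted 0.0054), with r = 0.82 after leaving out 2. The 75th percentile of the array gave r = -0.45 (exact permutation p = 0.22, adjusted p = 0.22) and rho = -0.38 (p = 0.31, adjusted 0.31), with r = 0.19 after leaving out 2. All tests were 2-sided, and the relations were chosen after seeing the data.

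**Figure D3:**
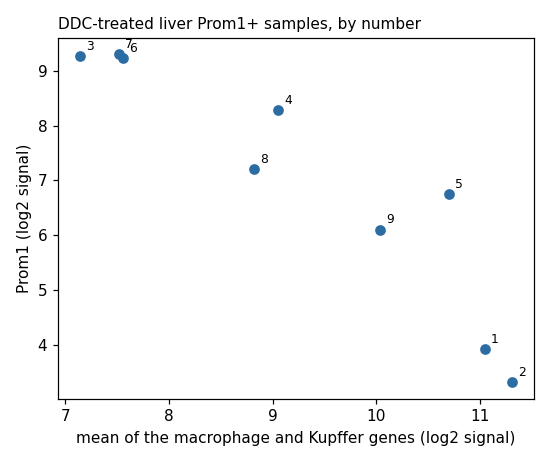
Prom1 level (log2, vertical axis) of the 9 DDC-treated liver samples against the mean log2 level of the macrophage genes (horizontal axis), 1 point per sample with its number. Prom1 is lowest, at 3.31 and 3.92, in samples 2 and 1.

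Set directly against each other, neonatal (n = 3) and DDC-treated (n = 9) liver cells differed in oncofetal genes and genes of the oxidative and xenobiotic response. Higher in neonatal cells were Igf2 (9.14 ± 0.31), Cyp3a16 (8.18 ± 0.17), Afp (7.02 ± 0.45), Peg3 (6.75 ± 0.53) and Bex1 (6.43 ± 0.72), the platelet genes Ppbp (8.18 ± 0.74) and Gp1bb (6.43 ± 0.59), Ngp (6.37 ± 0.37), and Hao2 (6.47 ± 0.38) and Sult2a2 (6.36 ± 0.48). Lower in neonatal cells were the acute phase genes Orm2 (-6.99 ± 0.64), Saa1 (-6.28 ± 0.74) and Saa2 (-6.86 ± 0.77), the xenobiotic enzymes Cyp2c29 (-8.68 ± 0.30), Cyp2b10 (-6.39 ± 0.82) and Gsta2 (-6.66 ± 0.54), the macrophage genes Mmp12 (-6.84 ± 0.63) and Gpnmb (-5.85 ± 0.62), and Thrsp (-6.25 ± 0.63) and Pigr (-5.91 ± 0.49), with adjusted p of 2.6e-07 or lower. Among oncofetal genes, 8 of 10 tested rose and 0 fell (9 and 0 adjusted over the list alone, median 4.74, adjusted p = 5.5e-17, adjusted p = 3.3e-05 with an estimated correlation). Among oxidative and xenobiotic response genes, 0 of 15 tested rose and 9 fell (0 and 10 adjusted over the list alone, median -1.75, adjusted p = 6.0e-11, adjusted p = 0.030 with an estimated correlation). Among proliferation genes, 19 of 20 tested rose and 0 fell (20 and 0 adjusted over the list alone, median 2.01, adjusted p = 1.8e-10, adjusted p = 0.37 with an estimated correlation). Of the neutrophil markers, 6 of 7 tested rose and 0 fell (6 and 0 adjusted over the list alone, median 3.72, adjusted p = 1.4e-07, adjusted p = 0.042 with an estimated correlation), and of the erythroid markers, 3 of 6 tested rose and 0 fell (3 and 0 adjusted over the list alone, median 1.68, adjusted p = 0.0013, adjusted p = 0.029 with an estimated correlation). The call total was 1363 of 10891 genes, 888 higher and 475 lower in neonatal cells.

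Neonatal and DDC-treated cells were compared with the same 5 untreated samples, and many genes were called in both. Both comparisons called 1195 genes higher, where 349.3 would be called in both if the lists were independent, which shared controls prevent, and 395 genes lower, where 53.8 would be. Another 24 genes were called in opposite directions. Across genes, which are not independent replicates, the log2 differences correlated with r = 0.71, and in 100 simulations of groups with no difference against the same controls r ran from -0.57 to 0.91 with a median of 0.54. When the untreated samples were split 2 and 3 between the comparisons, in 20 ways, 735 to 1315 genes were called the same way in both, and r was 0.17 to 0.64.

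Tumours were next compared with sorted cells of the same organ. Tumours were dissected whole and extracted with a column kit, while sorted cells were dissociated, sorted and extracted with a kit for small samples, so the protocol and the tumour state changed together in every one of these comparisons. In HCC/CC (n = 14) against untreated liver cells (n = 5), Lcn2 was 12.78 ± 0.63 against 4.74 ± 1.58, a difference of 8.04 ± 0.46. Other genes that rose were Ubd (6.61 ± 0.72), Ly6d (6.21 ± 0.34), Cpe (5.41 ± 0.87), Rragd (5.15 ± 0.76), Wfdc2 (5.07 ± 0.45) and Osbpl3 (4.84 ± 0.30), the transcription factor Sox4 (4.87 ± 0.56) and Gt(ROSA)26Sor (4.77 ± 0.46). Genes that fell were Hsd3b5 (-7.75 ± 0.18), Mup3 (-7.10 ± 1.57), Elovl3 (-6.45 ± 0.40), Hsd3b2 (-4.58 ± 0.65) and Sult5a1 (-4.32 ± 0.50), the liver sinusoid genes Dnase1l3 (-4.59 ± 0.70), Clec4g (-4.48 ± 0.93) and Wnt2 (-4.05 ± 0.53), and the immediate early factor Fos (-4.46 ± 0.47). Adjusted p was 0.0015 or lower for these genes.

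Among extracellular matrix genes, 12 of 16 tested rose and 0 fell (13 and 0 adjusted over the list alone, median 1.90, adjusted p = 6.3e-04, adjusted p = 0.57 with an estimated correlation), among them Col3a1 (3.91 ± 0.52) and Lum (3.85 ± 0.52). Among proliferation genes, 13 of 19 tested rose and 0 fell (13 and 0 adjusted over the list alone, median 1.36, adjusted p = 0.0054, adjusted p = 0.73 with an estimated correlation). Examples were Ube2c (2.92 ± 0.56) and Mki67 (2.20 ± 0.54). Among hypoxia and glycolysis genes, 7 of 15 tested rose and 0 fell (7 and 0 adjusted over the list alone, median 1.27, adjusted p = 0.025, adjusted p = 0.55 with an estimated correlation). Examples were Egln3 (3.99 ± 0.43) and Hk2 (2.98 ± 0.51). Among endothelial markers, 1 of 14 tested rose and 10 fell (1 and 10 adjusted over the list alone, median -1.70, adjusted p = 4.2e-05, adjusted p = 0.55 with an estimated correlation). Examples were Ptprb (-3.08 ± 0.47) and Kdr (-2.95 ± 0.51). Among immediate early genes, 3 of 16 tested rose and 10 fell (3 and 10 adjusted over the list alone, median -1.57, adjusted p = 2.2e-05, adjusted p = 0.32 with an estimated correlation). Among bile acid and cytochrome P450 genes, 0 of 14 tested rose and 5 fell (0 and 5 adjusted over the list alone, median -1.40, adjusted p = 1.9e-04, adjusted p = 0.41 with an estimated correlation). Examples were Cyp8b1 (-4.15 ± 0.89) and Cyp7b1 (-3.48 ± 0.62). The actin 3' minus 5' difference was 0.87 ± 0.19 in tumours and 1.45 ± 0.25 in cells. There were 2615 called genes of 11075, 1925 higher and 690 lower (73.6% higher), and 1429 higher and 994 lower (59.0%) after quantile normalization, which moved the median of all genes from 0.30 to 0.11. The count was 1149 with only samples whose title number was at most 300, 1188 with the actin difference as a covariate and 874, of which 29.5% were higher, with liver sample 1 as the only control, the last 2 chosen after seeing the data.

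Hepatoblastoma (n = 2), a liver tumour of early life, was compared with neonatal liver cells (n = 3). In the full fit the acute phase genes Saa1 (7.30 ± 0.40) and Saa2 (8.41 ± 0.38), the estrogen sulfotransferase Sult1e1 (7.22 ± 0.30), the desaturase Scd1 (6.48 ± 0.46), the glutamate transporter Slc1a2 (6.15 ± 0.25), and Gstm2 (6.08 ± 0.49), Pigr (5.91 ± 0.45) and Ildr2 (5.68 ± 0.34) rose. Afp (-7.60 ± 1.27), the fetal RNA-binding protein gene Igf2bp3 (-6.26 ± 0.20), Epcam (-6.44 ± 0.56), Marco (-6.79 ± 0.57), Ngp (-6.62 ± 0.70), Fos (-6.42 ± 0.77), and Bex4 (-6.52 ± 0.20), Tff3 (-6.40 ± 0.57) and Scara3 (-6.28 ± 0.26) fell, with adjusted p of 0.026 or lower. Among zonal Wnt targets of liver, 5 of 10 tested rose and 0 fell (7 and 0 adjusted over the list alone, median 3.37, adjusted p = 3.9e-04, adjusted p = 0.53 with an estimated correlation). Examples were Lgr5 (4.18 ± 0.86) and Rhbg (4.15 ± 1.11, not called). Among general Wnt targets, 5 of 12 tested rose and 0 fell (6 and 0 adjusted over the list alone, median 2.37, adjusted p = 0.0018, adjusted p = 0.37 with an estimated correlation). Examples were Sp5 (4.47 ± 0.45) and Nkd1 (3.41 ± 0.62). Among proliferation genes, 0 of 20 tested rose and 12 fell (0 and 19 adjusted over the list alone, median -2.57, adjusted p = 2.2e-08, adjusted p = 0.61 with an estimated correlation). Among oncofetal genes, 0 of 10 tested rose and 4 fell (0 and 6 adjusted over the list alone, median -4.34, adjusted p = 8.4e-05, adjusted p = 0.23 with an estimated correlation). Markers of other cell types moved with these: among cholangiocyte markers, 0 of 11 tested rose and 6 fell (0 and 8 adjusted over the list alone, median -2.70, adjusted p = 1.2e-04, adjusted p = 0.61 with an estimated correlation), and among endothelial markers, 0 of 14 tested rose and 6 fell (0 and 8 adjusted over the list alone, median -1.02, adjusted p = 1.9e-04, adjusted p = 0.55 with an estimated correlation). Among immediate early genes, 0 of 16 tested rose and 10 fell (0 and 12 adjusted over the list alone, median -2.29, adjusted p = 5.4e-07, adjusted p = 0.53 with an estimated correlation). In total 1369 of 11018 genes were called, 537 higher and 832 lower. That number rests on single samples: with limma it was 0 without neonatal liver sample 1 or 3 (2247 and 2254 genes at an unadjusted p under 0.05), 480 without neonatal sample 2, 3587 without hepatoblastoma 1 and 2671 without hepatoblastoma 2, so every gene call named here was lost without at least 1 sample. It was also 500 with array weights and, in a fit chosen after seeing the data, 2565 with the actin difference as a covariate.

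Prostatic adenocarcinoma (n = 8) was compared with prostate cells (n = 3). Msmb, a major prostatic secretion, was 4.00 ± 2.67 against 13.11 ± 0.29 (-9.11 ± 1.40), and Sbp (-9.20 ± 1.83), Spink1 (-8.00 ± 1.91), Pate14 (-7.58 ± 1.24) and Scgb2b27 (-6.50 ± 1.07), Retnla (-7.12 ± 1.24), the chemokine Ccl4 (-6.67 ± 0.31), Fosb (-6.79 ± 0.27) and Cyp4a12a (-6.55 ± 0.42) also fell. Genes that rose included Prr9 (7.45 ± 0.41), Tchh (7.14 ± 0.49), Ly6d (6.47 ± 0.33), Sprr2h (5.94 ± 0.62) and Dmkn (5.60 ± 0.78), beside the defensin Defa21 (7.52 ± 0.47), the Wnt regulator Dkk2 (6.55 ± 1.08), the matrix gene Tnc (5.25 ± 1.01), and Cryba4 (5.24 ± 0.62) and Ctse (5.20 ± 0.52). The largest adjusted p among these was 0.0069. Among prostate luminal markers, 0 of 12 tested rose and 8 fell (0 and 8 adjusted over the list alone, median -2.75, adjusted p = 0.086, adjusted p = 0.37 with an estimated correlation), so this list was not called. Among Wnt targets, 8 of 13 tested rose and 0 fell (8 and 0 adjusted over the list alone, median 1.90, adjusted p = 0.0098, adjusted p = 0.67 with an estimated correlation). Examples were Apcdd1 (4.43 ± 0.76) and Rnf43 (2.88 ± 0.29). Among proliferation genes, 19 of 20 tested rose and 0 fell (20 and 0 adjusted over the list alone, median 2.18, adjusted p = 1.8e-04, adjusted p = 0.69 with an estimated correlation). Tumour 8 stood apart, with a proliferation score of 3.46 against 6.10 to 7.36 in the other tumours and 3.88 in prostate cells, and with the highest actin (1.002) and Gapdh (0.95) 3' minus 5' differences of the group. Among keratinocyte differentiation genes, 6 of 8 tested rose and 0 fell (6 and 0 adjusted over the list alone, median 3.28, adjusted p = 0.026, adjusted p = 0.48 with an estimated correlation). Examples were Ivl (5.09 ± 0.43) and Lor (3.75 ± 0.80). Among extracellular matrix genes, 12 of 16 tested rose and 0 fell (13 and 0 adjusted over the list alone, median 3.06, adjusted p = 0.0013, adjusted p = 0.67 with an estimated correlation), and among smooth muscle markers, 5 of 8 tested rose and 0 fell (6 and 0 adjusted over the list alone, median 2.57, adjusted p = 0.0055, adjusted p = 0.59 with an estimated correlation). Among cytokine and chemokine genes, 3 of 15 tested rose and 11 fell (3 and 11 adjusted over the list alone, median -3.08, adjusted p = 5.7e-06, adjusted p = 0.47 with an estimated correlation). Among macrophage markers, 0 of 11 tested rose and 7 fell (0 and 8 adjusted over the list alone, median -1.44, adjusted p = 7.7e-04, adjusted p = 0.55 with an estimated correlation). Among immediate early genes, 0 of 17 tested rose and 14 fell (0 and 14 adjusted over the list alone, median -2.41, adjusted p = 1.0e-10, adjusted p = 0.25 with an estimated correlation). Actin 3' minus 5' was 0.72 ± 0.13 in tumours and 1.05 ± 0.12 in cells. There were 2316 called genes of 10981, 1362 higher and 954 lower (58.8% higher), and 1008 higher and 1243 lower (44.8%) after quantile normalization, with a median of all genes of 0.14 and -0.03. With the actin difference as a covariate, chosen after seeing the data, the count was 888.

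Gastric adenoma (n = 7) was compared with stomach cells (n = 2). Genes that rose included the ion channel gene Otop3 (6.04 ± 0.52), the transcription factor Onecut2 (5.97 ± 0.50), the matricellular gene Ccn2 (5.46 ± 0.87), smooth muscle actin Acta2 (5.25 ± 0.52) and Ogn (5.005 ± 0.69). Genes that fell included Krtdap (-4.72 ± 0.91), Chst4 (-4.10 ± 0.51) and Klb (-3.96 ± 0.30) and the immediate early genes Fosb (-4.42 ± 0.33) and Nr4a1 (-4.02 ± 0.52), with adjusted p of 0.0091 or lower in both directions. Among extracellular matrix genes, 13 of 15 tested rose and 0 fell (13 and 1 adjusted over the list alone, median 3.45, adjusted p = 1.8e-07, adjusted p = 0.50 with an estimated correlation). Examples were Dcn (4.92 ± 0.61) and Postn (4.85 ± 0.77). Among smooth muscle markers, 5 of 6 tested rose and 0 fell (6 and 0 adjusted over the list alone, median 3.14, adjusted p = 5.6e-04, adjusted p = 0.44 with an estimated correlation). Among chief and neck cell markers, 0 of 8 tested rose and 1 fell (0 and 1 adjusted over the list alone, median -2.33, adjusted p = 0.0024, adjusted p = 0.25 with an estimated correlation). The call of Gast (5.13 ± 2.54 against 13.03 ± 0.66) was lost without either stomach sample, with differences from -8.51 to -7.44 over all samples left out. Among immediate early genes, 0 of 17 tested rose and 10 fell (0 and 10 adjusted over the list alone, median -1.73, adjusted p = 1.8e-08, adjusted p = 0.029 with an estimated correlation). In all 1220 of 10960 genes were called, 884 higher and 336 lower (72.5% higher), and 610 higher and 615 lower (49.8%) after quantile normalization, which moved the median of all genes from 0.11 to -0.09. Without stomach sample 2 the number was 797, and with array weights 730.

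Small intestinal adenoma (n = 3) was compared with small intestinal cells (n = 3). The plasminogen activator Plat was 10.19 ± 0.95 against 3.02 ± 0.40 (7.17 ± 0.48), and Tnfrsf11b (6.62 ± 0.32), Etv5 (6.40 ± 0.47), Rgs5 (6.32 ± 0.51), Cybrd1 (6.17 ± 0.57), Wfdc18 (6.15 ± 0.92), Anxa1 (6.06 ± 0.41), Acta2 (6.05 ± 0.37) and Actg2 (5.88 ± 0.22) and the Wnt feedback gene Nkd1 (5.97 ± 0.47) rose. The pancreatic enzymes Amy2a5 (-8.34 ± 0.49) and Cela2a (-6.66 ± 0.60), the cytochromes Cyp3a11 (-7.57 ± 0.87), Cyp2b10 (-7.31 ± 0.51) and Cyp3a25 (-6.93 ± 1.22), the glucuronosyltransferases Ugt2b5 (-7.52 ± 0.41) and Ugt2a3 (-6.49 ± 0.44), and Arg2 (-6.88 ± 1.25), Apoc3 (-6.86 ± 1.14) and Rdh7 (-6.61 ± 0.56) fell. Adjusted p was 0.0077 or less. Pancreas in sorted cells was not excluded for Amy2a5 and Cela2a. Among Wnt targets, 13 of 15 tested rose and 0 fell (14 and 0 adjusted over the list alone, median 2.23, adjusted p = 2.2e-06, adjusted p = 0.46 with an estimated correlation). Examples were Notum (5.21 ± 0.59) and Tnfrsf19 (4.84 ± 0.50). Among MAPK output genes, 10 of 12 tested rose and 0 fell (10 and 0 adjusted over the list alone, median 2.36, adjusted p = 5.5e-06, adjusted p = 0.25 with an estimated correlation). Examples were Dusp4 (4.24 ± 0.33) and Phlda1 (3.23 ± 0.36). Among enterocyte markers, 0 of 12 tested rose and 10 fell (0 and 11 adjusted over the list alone, median -4.60, adjusted p = 4.8e-06, adjusted p = 0.54 with an estimated correlation). Examples were Treh (-6.17 ± 0.67) and Anpep (-5.89 ± 0.43). Among enteroendocrine markers, 0 of 11 tested rose and 9 fell (0 and 11 adjusted over the list alone, median -2.35, adjusted p = 2.7e-06, adjusted p = 0.37 with an estimated correlation). Examples were Gip (-5.07 ± 1.12) and Gcg (-4.48 ± 0.28). Among extracellular matrix genes, 15 of 15 tested rose and 0 fell (15 and 0 adjusted over the list alone, median 3.94, adjusted p = 6.9e-09, adjusted p = 0.46 with an estimated correlation). Of the smooth muscle markers, 6 of 7 tested rose and 0 fell (6 and 0 adjusted over the list alone, median 4.32, adjusted p = 1.8e-04, adjusted p = 0.18 with an estimated correlation). Actin 3' minus 5' was 0.59 ± 0.09 in tumours and 0.99 ± 0.26 in cells. The comparison called 2439 of 11076 genes, 1505 higher and 934 lower (61.7% higher), and 1192 higher and 1189 lower (50.1%) after quantile normalization, with a median of all genes of 0.12 and -0.06. It called 770 with the actin difference as a covariate, chosen after seeing the data.

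Uterine carcinoma (n = 3) was compared with uterine cells (n = 4). Fosb was 2.82 ± 0.11 against 10.71 ± 0.36 (-7.89 ± 0.22), and the kallikrein Klk1 (-7.41 ± 1.61), the class II gene H2-Eb1 (-7.12 ± 0.76), the chemokines Ccl7 (-6.73 ± 0.64), Ccl4 (-6.66 ± 0.34) and Ccl3 (-6.24 ± 0.26), the cytokine Il6 (-6.40 ± 0.29) and the macrophage genes Retnla (-6.39 ± 0.33), F13a1 (-6.21 ± 0.57) and Folr2 (-5.91 ± 0.43) also fell. The haemoglobin gene Hba-a1 (7.53 ± 0.70), Serpinb7 (6.69 ± 0.61) and Igfbp2 (6.37 ± 0.28), the stem cell gene Olfm4 (4.87 ± 0.84), the transcription factor Sox11 (4.41 ± 0.35), and Col8a1 (4.44 ± 0.53), Vnn1 (4.39 ± 0.61), Aqp4 (4.13 ± 0.63) and Moxd1 (4.11 ± 0.25) rose. Adjusted p was at most 0.012 for these. Of the macrophage markers, 0 of 11 tested rose and 11 fell (0 and 11 adjusted over the list alone, median -3.21, adjusted p = 1.1e-08, adjusted p = 0.33 with an estimated correlation). Examples were Mrc1 (-5.24 ± 0.65) and Csf1r (-4.04 ± 0.37). Among cytokine and chemokine genes, 0 of 16 tested rose and 11 fell (1 and 11 adjusted over the list alone, median -3.88, adjusted p = 6.2e-08, adjusted p = 0.40 with an estimated correlation). Among immediate early genes, 0 of 16 tested rose and 15 fell (0 and 15 adjusted over the list alone, median -3.95, adjusted p = 1.1e-16, adjusted p = 0.24 with an estimated correlation). Among proliferation genes, 20 of 21 tested rose and 0 fell (20 and 0 adjusted over the list alone, median 1.68, adjusted p = 8.9e-08, adjusted p = 0.55 with an estimated correlation). Examples were Bub1b (2.63 ± 0.38) and Cenpf (2.26 ± 0.27). The total was 2040 called genes of 10906, 935 higher and 1105 lower. Of 46 lists tested here, 6 were called, and 0 with an estimated correlation.

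Lung adenocarcinoma (n = 2) was compared with lung cells (n = 4). Lcn2 was 12.76 ± 0.09 against 4.86 ± 1.41 (7.90 ± 0.83), and Kng1 (7.88 ± 0.58), Chil1 (7.50 ± 0.82), Cd177 (7.18 ± 0.90), Dmkn (6.86 ± 0.61), Ckmt1 (6.68 ± 0.61), Tc2n (6.58 ± 0.64), Lamb3 (6.52 ± 0.67) and Egfl6 (6.46 ± 0.80) and the imprinted RNA Meg3 (7.39 ± 0.65) rose. The chemokines Cxcl1 (-8.71 ± 0.66), Cxcl2 (-7.27 ± 0.59), Ccl7 (-7.18 ± 0.69), Ccl2 (-6.95 ± 0.65) and Cxcl13 (-6.76 ± 0.81), Il6 (-6.86 ± 0.72) and the macrophage genes Clec10a (-6.89 ± 0.62), Fcna (-6.83 ± 0.64), Folr2 (-6.70 ± 0.65) and F13a1 (-6.55 ± 0.61) fell. The largest adjusted p among these genes was 8.0e-04. Among alveolar type 2 markers, 7 of 10 tested rose and 0 fell (7 and 0 adjusted over the list alone, median 3.32, adjusted p = 1.5e-04, adjusted p = 0.22 with an estimated correlation). Examples were Slc34a2 (5.31 ± 0.76) and Sftpd (5.04 ± 0.66). Among macrophage markers, 0 of 12 tested rose and 7 fell (0 and 11 adjusted over the list alone, median -2.81, adjusted p = 6.0e-11, adjusted p = 0.33 with an estimated correlation), and among endothelial markers, 0 of 14 tested rose and 2 fell (0 and 6 adjusted over the list alone, median -1.97, adjusted p = 2.1e-06, adjusted p = 0.58 with an estimated correlation). Among cytokine and chemokine genes, 1 of 15 tested rose and 11 fell (1 and 11 adjusted over the list alone, median -4.61, adjusted p = 4.7e-14, adjusted p = 0.33 with an estimated correlation). Among immediate early genes, 0 of 16 tested rose and 11 fell (0 and 13 adjusted over the list alone, median -2.21, adjusted p = 4.4e-19, adjusted p = 0.036 with an estimated correlation). The called genes were 908 of 11195, 642 higher and 266 lower (70.7% higher), and 564 higher and 435 lower (56.5%) after quantile normalization, with a median of all genes of 0.36 and 0.13. The number was 448 and 389 without tumour 1 and 2, 1505, 583 and 558 without lung cells 1, 2 and 4, and 401 without lung cells 3 and 4, the last chosen after seeing the data. It was 3628 with all other groups in the fit and 2461 with array weights.

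Across the 6 tumour comparisons of different organs, which share no sample, 44 genes were called in the same direction in at least 5. Of these, 30 were higher and 14 lower in tumours, where 0.40 of the 13126 genes tested in at least 1 comparison would be called if the comparisons were independent. Among the 9299 genes tested in all 6, a set chosen after seeing the data, 42 were called and 0.55 would be. Called in all 6 were Pde7a, a cyclic AMP phosphodiesterase, which rose by a mean of 1.62, and the immediate early genes Egr1 (mean -2.70), Fos (-3.29) and Fosb (-4.97), which fell. Called higher in 5 were Lcn2 (mean 4.82), Ly6d (4.21), Ccn2 (3.45), Tnc (3.25), Acta2 (3.19), Cald1 (2.90), Ajuba (2.89) and Egln3 (2.82). Lower in 5 were Atf3 (-3.33), Junb (-2.26), Jun (-2.07), Dusp1 (-2.33), Nr4a1 (-2.57) and the heat shock gene Hspa1b (-2.36). Of the 14 lower genes 8 stood in the immediate early list. Means cover all 6, called or not (Lcn2 0.06 in uterus, Acta2 -0.99 in lung). Sort and extraction differed between tumours and cells for both directions. The genes were chosen after their values were seen.

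Within the stomach, adenocarcinoma (n = 4) was compared with adenoma (n = 7). The cadherin Cdh2 was 8.35 ± 1.002 against 2.73 ± 0.16 (5.62 ± 0.44), and Nrn1 (6.90 ± 0.55), Prkg2 (6.79 ± 0.63), Nrk (6.68 ± 0.44), Mir100hg (5.59 ± 0.54), Tfr2 (5.36 ± 0.31), Cpxm1 (4.91 ± 0.71) and Tm4sf1 (4.80 ± 0.61), the cell cycle inhibitor locus Cdkn2a (5.41 ± 1.03) and Chil3 (5.30 ± 1.26) were higher. The mucus regulator Clca1 (-9.003 ± 0.85), Lypd8 (-9.40 ± 1.12), Gsdma2 (-8.04 ± 0.41), Pigr (-7.55 ± 0.83), Tmem30b (-7.48 ± 0.37), Ifit1bl1 (-7.29 ± 0.82), Psapl1 (-7.29 ± 1.12) and Psca (-7.12 ± 0.76), the intrinsic factor gene Cblif (-7.58 ± 0.43) and ghrelin, Ghrl (-7.15 ± 0.53), were lower. Adjusted p was 6.3e-04 or lower. Among gastric pit markers, 0 of 7 tested rose and 7 fell (0 and 7 adjusted over the list alone, median -4.79, adjusted p = 3.2e-07, adjusted p = 0.030 with an estimated correlation). Examples were Muc5ac (-5.77 ± 0.45) and Gkn1 (-4.79 ± 0.62). Among enteroendocrine markers, 0 of 7 tested rose and 6 fell (0 and 6 adjusted over the list alone, median -3.99, adjusted p = 8.9e-08, adjusted p = 0.016 with an estimated correlation). Among parietal cell markers, 0 of 7 tested rose and 7 fell (0 and 7 adjusted over the list alone, median -3.52, adjusted p = 4.5e-05, adjusted p = 0.24 with an estimated correlation). Examples were Atp4a (-4.21 ± 0.88) and Atp4b (-4.35 ± 0.63). Among genes of epithelial-mesenchymal transition, 9 of 11 tested rose and 0 fell (10 and 0 adjusted over the list alone, median 2.08, adjusted p = 1.5e-05, adjusted p = 0.25 with an estimated correlation). Examples were Twist1 (4.22 ± 0.38) and Vim (2.96 ± 0.45). Among macrophage markers, 9 of 11 tested rose and 0 fell (9 and 0 adjusted over the list alone, median 2.32, adjusted p = 0.0018, adjusted p = 0.40 with an estimated correlation). Among YAP targets, 7 of 11 tested rose and 0 fell (7 and 0 adjusted over the list alone, median 1.502, adjusted p = 0.011, adjusted p = 0.39 with an estimated correlation). The call total was 2759 of 10968 genes, 1506 higher and 1253 lower.

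Between liver tumours, hepatoblastoma (n = 2) was compared with HCC/CC (n = 14). Lgr5, a Wnt target and stem cell receptor, was 8.68 ± 0.76 against 3.32 ± 0.47 (5.36 ± 0.75), and the pericentral transporters Slc1a2 (5.26 ± 0.52) and Rhbg (4.83 ± 0.64), the imprinted RNAs Meg3 (7.12 ± 1.15), Mirg (4.72 ± 0.41) and Rian (4.59 ± 0.79), and Fmn2 (4.72 ± 0.27), Avpr1a (4.68 ± 0.49) and Upk3a (4.61 ± 0.85) were higher. Klhl13 (-4.19 ± 0.63), Tmem184c (-4.11 ± 0.47), Shtn1 (-4.05 ± 0.28) and Osbpl3 (-4.04 ± 0.46) were lower, with adjusted p of 2.3e-04 or less for all of these. Among zonal Wnt targets, 9 of 10 tested rose and 0 fell (10 and 0 adjusted over the list alone, median 3.81, adjusted p = 3.2e-15, adjusted p = 0.0090 with an estimated correlation), with Cyp1a2 (4.08 ± 0.87) among them. Among general Wnt targets, 6 of 12 tested rose and 0 fell (8 and 0 adjusted over the list alone, median 2.39, adjusted p = 7.1e-07, adjusted p = 0.27 with an estimated correlation). Examples were Axin2 (3.60 ± 0.63) and Nkd1 (3.05 ± 0.77). The called genes were 658 of 10808, 353 higher and 305 lower. Their number was 1031 without hepatoblastoma 2, 186 in a fit of only these groups and 74 with array weights.

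Large intestinal adenoma (n = 5) was compared with small intestinal adenoma (n = 3). The carbonic anhydrase Car1 was 11.69 ± 2.74 against 3.12 ± 0.08 (8.56 ± 0.93), and the goblet cell product Retnlb (7.21 ± 0.69), the peptide hormone gene Guca2a (5.62 ± 1.104), and Tmigd1 (7.11 ± 0.40), Clca4a (6.50 ± 0.63) and Pmp22 (5.66 ± 0.64) were higher. Gkn3, a gastrokine, was lower (-8.46 ± 1.32), as were Cfi (-6.52 ± 0.67), Igfbp1 (-5.91 ± 0.86), Cybrd1 (-5.88 ± 1.27), Sbspon (-4.94 ± 0.89) and Krt23 (-4.66 ± 1.04) and the Wnt targets Tnfrsf19 (-5.51 ± 0.86), Nkd1 (-5.44 ± 0.74) and Notum (-5.40 ± 0.68). No adjusted p among them exceeded 0.0013. Among Wnt targets, 0 of 14 tested rose and 11 fell (0 and 12 adjusted over the list alone, median -3.20, adjusted p = 6.0e-11, adjusted p = 0.16 with an estimated correlation), including Lgr5 (-4.05 ± 0.72). Among intestinal stem cell genes, 0 of 9 tested rose and 6 fell (0 and 6 adjusted over the list alone, median -2.83, adjusted p = 1.7e-04, adjusted p = 0.23 with an estimated correlation). Examples were Ascl2 (-3.36 ± 0.57) and Axin2 (-3.23 ± 0.61). Among gastric pit markers, 0 of 6 tested rose and 4 fell (1 and 4 adjusted over the list alone, median -3.44, adjusted p = 0.0015, adjusted p = 0.25 with an estimated correlation). Among extracellular matrix genes, 5 of 16 tested rose and 0 fell (10 and 0 adjusted over the list alone, median 1.803, adjusted p = 1.9e-04, adjusted p = 0.57 with an estimated correlation), and among endothelial markers, 6 of 12 tested rose and 0 fell (8 and 0 adjusted over the list alone, median 1.45, adjusted p = 8.8e-06, adjusted p = 0.37 with an estimated correlation). The comparison called 1405 of 10874 genes, 718 higher and 687 lower, and 857 and 746 without small intestinal adenoma 1 and 3. It called 934 with a filter at the 60th percentile.

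Perineal (n = 4) and perioral (n = 3) squamous cell carcinoma differed in fewer genes. The positional gene Hoxa9 was 7.59 ± 0.29 against 3.45 ± 0.20 (4.14 ± 0.49), and Ugt8a (7.89 ± 1.02), Adh1 (4.80 ± 0.80), Calcb (4.52 ± 0.87), Actg2 (4.29 ± 0.76), Ephx2 (4.07 ± 0.85), Lrmp (3.93 ± 0.62) and Tlcd4 (3.82 ± 0.83) and the adipogenic receptor Pparg (3.89 ± 0.63) were higher in perineal tumours. The hair keratin Krt27 (-4.44 ± 0.36), the keratin-associated Krtap4-16 (-4.64 ± 0.48) and Gm11559 (-4.70 ± 0.34) and Odam (-4.49 ± 0.26) were lower, with adjusted p of 0.0018 or lower throughout. Among smooth muscle markers, 3 of 7 tested rose and 0 fell (5 and 0 adjusted over the list alone, median 2.19, adjusted p = 3.4e-06, adjusted p = 0.22 with an estimated correlation). Examples were Cnn1 (3.41 ± 0.92) and Mylk (2.19 ± 0.47). Among skeletal muscle markers, 0 of 10 tested rose and 3 fell (0 and 3 adjusted over the list alone, median -1.53, adjusted p = 2.5e-05, adjusted p = 0.44 with an estimated correlation). Examples were Myh1 (-4.23 ± 0.99) and Myh4 (-3.68 ± 0.53). The called genes were 357 of 10688, 166 higher and 191 lower, and 1155 with array weights.

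Each tumour was correlated with the mean of the sorted cells of 6 organs after centring. Of 43 tumours, 36 were nearest to their own organ (permutation p = 1.0e-05, the smallest the permutations can give). All 14 HCC/CC, 2 hepatoblastomas, 7 gastric adenomas, 3 uterine carcinomas and 2 lung adenocarcinomas were nearest to their own organ, as were 6 of 8 prostatic adenocarcinomas and 2 of 3 small intestinal adenomas. None of the 4 gastric adenocarcinomas was (0 of 4): samples 2 and 3 were nearest to lung cells and 1 and 4 to uterine cells, and their correlation with stomach cells ran from -0.14 to 0.07. Mean correlations with the own organ were 0.54 in gastric adenoma, 0.63 in HCC/CC, 0.67 in hepatoblastoma and 0.435 in prostatic adenocarcinoma. Genes are not independent replicates, tumours of a type may not be, and whole tumours may hold normal tissue of the organ.

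Each of the 7 metastases, which were single samples and allow no test, was set against the mean of every primary tumour type. Those of gastric origin were nearest to gastric adenocarcinoma, with r of 0.79 (abdomen) and 0.74 (liver). Hepatoblastoma in lung was nearest to hepatoblastoma (0.89), HCC/CC in intestine and lung to HCC/CC (0.65 and 0.49), and uterine carcinoma in the abdomen to uterine carcinoma (0.57). Uterine carcinoma in the liver was nearest to HCC/CC (0.31), ahead of uterine carcinoma (0.21), but with Spearman correlation and without centring it was nearest to uterine carcinoma (0.31 and 0.93).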

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

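The tests of explanations for the 3 patterns weighed here were chosen only after the results were seen. Samples far from the rest of their group were looked for in 50 combinations of a measure and a group of 4 to 9 samples, and 9 stood apart, where chance alone gives about 1 in 20, or 2.5. Prostatic adenocarcinoma 8 stood apart in its actin 3' minus 5' difference (1.002, others 0.61 to 0.78), its Gapdh difference (0.95, others 0.38 to 0.57) and its proliferation score (3.46, others 6.10 to 7.36). Prom1 was 2.87 in gastric adenoma 3, with the other 6 at 9.88 to 11.93, and 5.30 in lung cells 3, with the others at 6.603 to 6.789. Uterus cells 3 had a 75th percentile of 6.61 (others 6.63), uterus cells 4 an actin difference of 0.41 (others 0.89 to 0.99) and kidney cells 4 a proliferation score of 3.84 (others 3.71 to 3.72). The 75th percentile of untreated liver sample 1 was 6.53, with the others at 6.13 to 6.22.

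Against untreated liver cells more genes were called higher than lower in neonatal cells, DDC-treated cells and HCC/CC. Scaling as the whole cause was argued against, as 58.3%, 59.2% and 59.0% of calls were still higher after quantile normalization. A 3' bias as the whole cause was argued against for neonatal (69.0% higher) and DDC-treated cells (74.2%) with the actin difference as a covariate, and cannot be told apart for HCC/CC (58.6%), where the covariate took the count of called genes from 2615 to 1188. A lower signal of untreated samples 2 to 5 stays open, as the fits with sample 1 as the only control (29.5% higher in HCC/CC, 59.0% in neonatal and 52.8% in DDC-treated cells) rest on 1 control library. Cells kept by the sort, age, treatment and tumour stay open and were not tested.

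Prom1 ran from 3.31 to 9.31 over the DDC-treated samples. RNA degradation was argued against, as Prom1 was higher where the actin difference was higher (r = 0.887), and array scaling cannot be told apart with 9 samples (r = -0.451). Macrophages among the sorted cells are a candidate source (r = -0.928). The bead sort against Prominin1 should remove cells without it. Yet sorted cells of untreated liver held Prom1 at only 3.45 ± 0.67, under the filter value of 4.06. None of the 14 list genes stands in another list, and the most abundant in DDC-treated cells were Vsig4 (11.01), Mrc1 (10.73), C1qb (10.70) and Cd5l (10.58), against 10.15, 10.81, 9.85 and 10.71 in untreated cells. No biological explanation was tested.

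The immediate early list was called lower in 5 of 6 tumour comparisons, which held with an estimated correlation in gastric adenoma (adjusted p = 0.029) and lung (adjusted p = 0.036) but not in HCC/CC (adjusted p = 0.32), prostatic (adjusted p = 0.25) or uterine tumours (adjusted p = 0.24). Array scaling was argued against, as the median stayed under -1 in 5 after quantile normalization. Macrophages among the sorted cells were argued against for gastric adenoma, where their markers had a median difference of 1.41, and may contribute in HCC/CC, prostatic, uterine and lung tumours, where the highest of 4 medians was -0.57. Dissociation and sorting cannot be told apart from the tumour state, as only sorted cells were dissociated in all 6 comparisons (5 called lower). The tumour state itself stays open and was not tested.

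Differences between comparisons were tested for 50 lists and 15 pairs of tumour comparisons (750 tests, 176 with an adjusted p under 0.05), and 9 joined calls of opposite direction. Small intestinal minus lung tumours differed by 2.87 in stellate cell and fibroblast markers (adjusted p = 3.0e-04, limma), -2.88 in hepatocyte markers (adjusted p = 4.4e-04, limma), 2.13 in epithelial-mesenchymal transition (adjusted p = 0.0020, limma) and 2.83 in endothelial markers (adjusted p = 0.020, limma). Gastric adenoma minus lung tumours differed by 2.11 in epithelial-mesenchymal transition (adjusted p = 0.0020, limma) and 2.32 in stellate cell and fibroblast markers (adjusted p = 0.0027, limma). HCC/CC differed from small intestinal adenoma by -2.38 in endothelial markers (adjusted p = 0.016, limma), and from gastric adenoma by 1.38 in DNA replication (adjusted p = 0.017, limma), as did prostatic adenocarcinoma by 1.43 (adjusted p = 0.023, limma). None of the list calls behind these differences held with an estimated correlation. The periorbital squamous cell carcinoma, a single sample in no comparison, had a keratinocyte differentiation score of 12.30, above the highest sorted sample at 5.90 (stomach cells 2).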

How the results depend on the processing

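The tests on other splits, and the settings named here as added, were chosen after the results were seen. No paired analysis was possible because the labels pair no samples. Over the 22 counts of called genes, quantile normalization, median centring, no filter, the mean of probe sets, a robust prior and probe sets named for cross-hybridisation left out each kept the count within 1.5 times. Array weights gave 500 genes for hepatoblastoma against neonatal cells, 730 for gastric adenoma, 2461 for lung adenocarcinoma, 74 for hepatoblastoma against HCC/CC and 1155 for the squamous cell carcinomas. Other samples in the fit gave 3628 for lung adenocarcinoma and 186 for hepatoblastoma against HCC/CC, and the 60th percentile filter 934 for large against small intestinal adenoma. HCC/CC gave 1149 with title numbers up to 300, which uses fewer samples. Of the added settings, untreated liver sample 1 as the only control gave 1450 genes in neonatal cells, 430 after DDC and 874 in HCC/CC, with fewer samples. With the added actin covariate the counts were 1188 for HCC/CC, 2565 for hepatoblastoma, 888 for prostatic adenocarcinoma and 770 for small intestinal adenoma. Lung adenocarcinoma gave 401 without lung cells 3 and 4, also added. Leaving out DDC-treated samples 1 and 2, added as well, gave 2312 genes after DDC and 1341 in neonatal against DDC-treated cells. The cause of these moves was not tested.

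Leaving out each sample in turn gave 0 (without neonatal sample 1 or 3, with 2247 and 2254 genes at an unadjusted p under 0.05 in limma) to 3587 genes (without hepatoblastoma 1) for hepatoblastoma against neonatal cells. The range was 797 (without stomach cells 2) to 1399 for gastric adenoma, and 389 (without tumour 2) to 1505 (without lung cells 1) for lung adenocarcinoma. It was 580 to 1031 (without hepatoblastoma 2) for hepatoblastoma against HCC/CC, and 746 (without small intestinal adenoma 3) to 1434 for the intestinal adenomas. The cause was not tested, and where 1 sample was left in a group it was assumed to vary like the others. The other 17 counts stayed within 1.5 times. List calls numbered 35 with an estimated correlation, 503 with fry for 1 direction and 538 with fry for either, against 321, and none changed direction. Requiring all 6 comparisons left 4 shared tumour genes in place of 44. Splitting the untreated samples left at least 735 genes shared by neonatal and DDC-treated cells, against 1590. Of 331 named calls, 305 were kept in every setting and 286 with every sample left out, and 1 reversed: Chil4 in lung was -0.30 without probe sets named for cross-hybridisation. Tumours nearest their own organ numbered 30 to 36, and metastases nearest their primary type 6 or 7, the uterine metastasis in liver being the one that changed. Signal near background limits the size of differences: in untreated liver, where bacterial control probe sets without target averaged 2.95, Afp was at 2.80.

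Other splits of samples tested whether chance gives as many genes. In 1 of 100 splits, the real one, as many were called for DDC-treated cells (2372, highest other 2111), HCC/CC (2615, 235), prostatic adenocarcinoma (2316, 764) and gastric adenocarcinoma (2759, 1520). The same held, 1 of 100, for genes higher in kidney (2139, 992), liver (1324, 1164), lung (1677, 412), prostate (1369, 1257), salivary gland (1423, 612), small intestine (1870, 1600) and uterus (2003, 682). It held in 1 of 35 for uterine carcinoma (2040, 1) and the squamous cell carcinomas (357, 340), and in 1 of 56 for the intestinal adenomas (1405, 569). For neonatal against untreated cells 2 of 56 gave as many (3434), the other being 3939 with untreated samples 3 to 5 against the rest. For neonatal against DDC-treated cells 3 of 100 did (1363, highest other 2742), with DDC-treated samples 1, 2 and 5 as a group. Chance stays open for neonatal cells, where other splits gave more. For small intestinal adenoma 10 splits are too few (2439, highest other 0). Hepatoblastoma, lung adenocarcinoma, gastric adenoma and stomach cells were not split. Elsewhere chance was argued against, unadjusted over tests.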

Other observations

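Hepatocyte genes of the metastases were set beside those of the primary tumours. The score was 11.94 in hepatoblastoma in lung, against 11.47 in primary hepatoblastoma (n = 2), and 10.21 and 8.53 in HCC/CC in intestine and lung, against 11.28 in primary HCC/CC (n = 14). Uterine carcinoma in the liver scored 9.78, uterine carcinoma in the abdomen 3.73 and primary uterine carcinoma 3.82 (n = 3). Gastric adenocarcinoma in the liver scored 5.45 and in the abdomen 4.74, against 4.78 in the primary tumours (n = 4). Proliferation scores were 6.58 and 6.65 in the HCC/CC metastases, against 5.18 in the primary tumours. Each metastasis is 1 sample, so no difference was tested.

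Immediate early genes varied between sorted groups. Their score was 11.25 in salivary gland, 10.98 in uterus, 10.42 in prostate and 10.31 in lung, and 9.33 in stomach and 9.03 in neonatal liver. Kidney (7.63), small intestine (7.88), untreated liver (8.16) and DDC-treated liver (8.17) were lower. Primary tumour groups lay between 6.74 in hepatoblastoma and 8.04 in prostatic adenocarcinoma.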
